A study of Mus musculus with 6 samples.

How the data were processed

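RNA was measured in 6 whole colons, 3 from wild-type mice and 3 from mice labelled as knockouts for Tnfrsf1a, the gene for tumour necrosis factor receptor 1 (TNFR1). The labels give male animals of 12 weeks, 3 mice for each genotype, and the strain C57Bl/6J for every sample. Per the labels' protocols, RNA was extracted with a PureLink kit and libraries were made from polyadenylated RNA with the SMARTer Universal Low Input kit. The series' design text gives paired-end sequencing of 50 bases at an average of 30 M reads per sample.

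The authors deposited 1 table of TPM, a length-normalised transcript abundance that sums to the same total in each library whatever its depth. Per the submitters' processing notes, transcripts were quantified with kallisto 0.43.1, differences were tested with sleuth, and the genome build was mm10. The results of sleuth were not used here. The read depth behind each deposited TPM value is unknown, so no counting interval is given. The table held 132639 lines for 131206 transcripts. Of these lines, 1433 repeated a transcript under another gene number with the same values (largest difference 0 TPM), and each transcript was taken once. No value was listed for 43008 transcripts, which left 88198. Among those, 1380 had no gene and were left out of the tests. The remaining transcripts belonged to 30419 genes, of which 30133 had a position in the GENCODE M21 annotation of mm10. That annotation gave coordinates and gene types, and it may differ from the transcript set the authors used.

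The transcripts without a gene held 4.05, 27.4 and 2.79% of all TPM in wild-type replicates 1, 2 and 3, and 2.60, 7.23 and 1.86% in the knockout replicates. In wild-type replicate 2, a pair of them held 26.9%, which lowers the TPM of every other transcript in that library. Median-of-ratios factors over the genes tested were 1.13, 0.786 and 1.1 for wild type and 1.06, 0.918 and 1.07 for knockout. Adjusted p-values after this scaling are given beside the genes and transcripts where they bear on the call, and as a range for the gene lists.

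TPM were summed per gene and tested as log2(TPM + 0.5), without further scaling, in genes with a mean of at least 1 TPM over the 6 libraries. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a variance trend). P-values were adjusted by the Benjamini-Hochberg method and the threshold was 0.05. The same model was fitted to single transcripts. A log2 fold change on this scale understates the change of genes with low values. Single values were compared with two-sided exact permutation tests, for which 3 mice against 3 cannot give a p below 0.1.

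Before the data were examined, 44 gene lists with 718 genes were fixed, covering TNF signalling, other pathways of the colon, cell types of the colon wall and tissues that a dissection can carry along. The table held 709 of these genes. The 39 lists with at least 5 tested members were compared with all other genes by camera with a preset correlation of 0.01. Camera with an estimated correlation was run beside it, as was fry, which asks whether the genes of a list move one way on balance. Genes within 10 Mb of Tnfrsf1a were compared with all others by a two-sided Fisher's exact test.

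The rule for the genes named was also fixed before the data were examined. It took Tnfrsf1a, and in each direction the 10 genes past the threshold with the largest log2 fold change. These needed a mean of at least 2 TPM in the higher group, with no overlap between the groups. Predicted gene models, pseudogenes and single immunoglobulin segments were counted only. Where fewer than 10 passed, the ranking was filled by the smallest p. Up to 4 members of each list were taken, or the 2 with the smallest p where none passed. Any other gene is said to have been chosen after its values were seen.

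The model was tested on simulated data with the means and spreads of the 14284 tested genes. Among 100 genes changed by 1 on the log2 scale, 31% were recovered, and among 100 changed by 2, 90% were recovered. Of 14084 unchanged genes, 4 passed the threshold. With the spread after median-of-ratios scaling, the recovered shares were 78% and 91%, and 4 unchanged genes passed. For 31056 transcripts the recovered shares were 7% and 54%, and 5 of 30856 unchanged transcripts passed. Genes and transcripts were simulated as independent, without variation shared by many genes of a library. These counts therefore do not give the rate of false calls in the real libraries.

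The alternatives fixed in advance were pseudocounts of 0.1 and 1, no filter on low values, a filter at 5 TPM, median-of-ratios scaling, quantile normalization, no variance trend, robust variance estimation, the replicate number as a block, each library left out in turn, an adjusted p of 0.1, windows of 5 and 20 Mb, gene values from transcripts of at least 0.1 TPM, and TPM recomputed without immunoglobulin segments and mitochondrial genes. Rescaling over transcripts with a gene, limma array weights, and median-of-ratios scaling without wild-type replicate 2 were chosen after seeing the data.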

Results

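The transcriptome of the whole colon was compared between 3 wild-type mice and 3 mice labelled as Tnfrsf1a knockouts, all males of 12 weeks. The table gives TPM, so the depth of each library is unknown. At least 1 TPM was reached by 14623, 13697 and 14488 genes in wild-type replicates 1, 2 and 3, and by 14279, 13697 and 14336 genes in the knockout replicates. Libraries were closely related, with Pearson correlations of log2 values across genes between 0.971 and 0.987. Wild-type replicate 2 stood apart on the first principal component, which held 49.7% of the variance.

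The targeted gene was read first. Tnfrsf1a (ENSMUSG00000030341; mm10 chromosome 6, 125349362 to 125362484) encodes TNFR1, the main signalling receptor for TNF. Its full-length transcript was less abundant in all 3 knockout libraries, and a shorter transcript that begins further downstream rose 9.53-fold on the log2(TPM + 0.5) scale, which understates the change of low values. The shorter form lies mostly in exons of the full-length one, so reads can be shared and the separate values are uncertain. The full-length transcript, ENSMUST00000032491, has 10 exons and measured 67.6, 39.9 and 59.1 TPM in wild type against 23.5, 20.4 and 25.6 TPM in knockout. The means were 55.5 ± 14.2 and 23.2 ± 2.61 TPM (SD, n = 3), without overlap between the groups (exact permutation p = 0.1, the smallest possible). Its log2 fold change was −1.21 ± 0.22 (SE), with an adjusted p of 0.197 in limma over 31056 transcripts and 0.0168 after median-of-ratios scaling.

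The shorter transcript, ENSMUST00000125880 (125357371 to 125361105), begins inside exon 3 of the full-length form and is annotated as a target of nonsense-mediated decay. Only its exon at 125358276 to 125358391 lies outside the exons of the full-length form. The shorter transcript measured 1.1 ± 0.18 TPM in wild type and 14.8 ± 2.87 TPM in knockout (SD, n = 3). Its log2 fold change was 3.25 ± 0.24 (SE; limma, Benjamini-Hochberg adjusted p = 0.00124). A transcript that begins in exon 4, ENSMUST00000144524, had 0.17 ± 0.07 TPM in wild type and 1.81 ± 0.36 TPM in knockout, below the mean required for testing. Summed over transcripts, Tnfrsf1a measured 59.4 ± 13.9 TPM in wild type and 44.2 ± 6.77 TPM in knockout. The summed value did not pass the threshold (log2 fold change −0.41, limma adjusted p = 1; exact permutation p = 0.3). The part of the gene removed in these mice is not given in the sources used here, so only the single transcripts separated the genotypes as labelled.

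**Figure D1:**
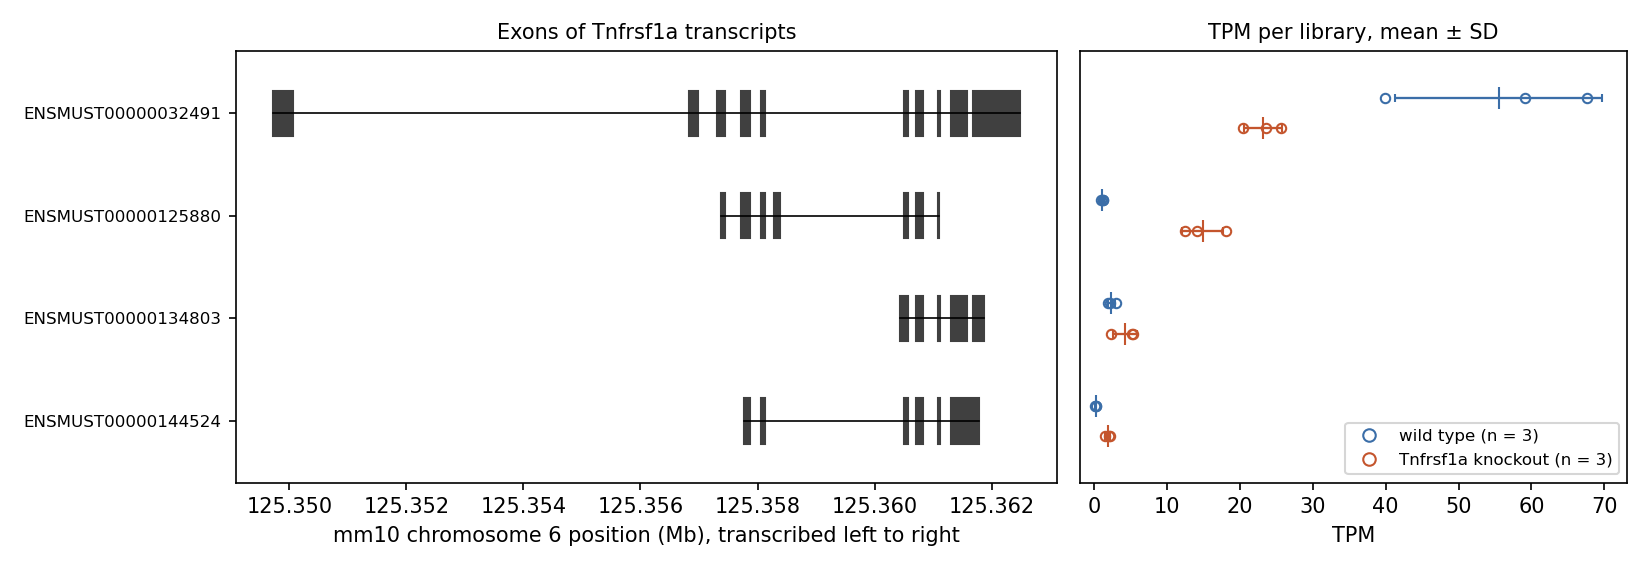
The left panel maps the exons of the 4 Tnfrsf1a transcripts that exceeded 1 TPM in any library on mm10 chromosome 6, and the right panel gives TPM per library (circles) with the mean and SD of each genotype (n = 3). The full-length transcript lay between 20.4 and 25.6 TPM in knockout against 39.9 to 67.6 TPM in wild type, and the transcript that begins in exon 3 lay at 12.4 TPM or more only in knockout.

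The comparison of all genes asks what differs in the colon between knockout and wild type. Nnt, Dynlt1b, Duoxa2 and Sprr2d rose in the knockout colon, both with TPM as deposited and after median-of-ratios scaling. Nnt encodes the mitochondrial nicotinamide nucleotide transhydrogenase, Duoxa2 the maturation factor of the hydrogen peroxide producing oxidase Duox2, Dynlt1b a dynein light chain and Sprr2d a small proline-rich protein of the epithelial envelope. Nnt was also among the genes fixed in advance as differing between substrains. A strain difference between the groups, if there is one, cannot be told apart from an effect of the knockout, for Nnt or for any other gene. S100a9, Hp, Il1f6 and Cfd also rose. The B cell chemokine Cxcl13, the retinoic acid degrading enzyme Cyp26b1 and the hair follicle genes Krt25, Tchh and Krtap5-1 fell. These genes passed the threshold with TPM as deposited and not after scaling, which left their log2 fold changes about as large.

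Of 14284 genes tested with limma, 13 were higher and 25 lower in the knockout at a Benjamini-Hochberg adjusted p below 0.05. After median-of-ratios scaling, 5 were higher and 1 lower, and all 6 were among the 38. These 6 were Nnt, Dynlt1b, Duoxa2, Sprr2d, the pseudogene Gm14292 and the predicted gene Gm21836, the last 2 chosen after their values were seen. Without wild-type replicate 2, 4 were higher and 15 lower, and 8 of these 19 were among the 38.

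Nnt (chromosome 13, 119335448 to 119408997) rose from 9.51 ± 2.36 to 27.4 ± 1.59 TPM (SD, n = 3), a log2 fold change of 1.51 ± 0.23 (SE, limma adjusted p = 0.000863, 0.00246 after scaling). Dynlt1b rose from 63.4 ± 13.9 to 138.8 ± 2.13 TPM (adjusted p = 0.00618, 0.00557 after scaling); it has close paralogs, so reads can be shared between copies and its level is uncertain. Duoxa2 rose from 5.75 ± 1.32 to 14.1 ± 1.72 TPM (adjusted p = 0.0109, 0.00666 after scaling). Sprr2d, a member of a family of similar genes and likewise uncertain, rose from 9.46 ± 3.33 to 27.5 ± 3.51 TPM (adjusted p = 0.00151, 0.0423 after scaling). Duoxa2 did not pass without wild-type replicate 2 (log2 fold change 1.053, limma adjusted p = 0.087). Neither Duoxa2 nor Sprr2d passed after rescaling over transcripts with a gene, chosen after seeing the data (adjusted p = 0.0571 and 0.109). Their log2 fold changes were then 1.125 and 1.43, against 1.24 and 1.549 in the main fit. With no filter on low values none of Nnt, Dynlt1b, Duoxa2 and Sprr2d passed (adjusted p = 0.384, 0.537, 0.651 and 0.703), though their log2 fold changes were the same.

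The other genes named on the higher side passed the threshold with TPM as deposited and not after scaling. Scaling left their log2 fold changes about as large. For S100a9, Cfd, Hp, Il1f6 and Clca4b they were 1.51, 1.507, 1.635, 1.407 and 1.227 after scaling. Before it they were 1.537, 1.535, 1.643, 1.423 and 1.264. S100a9, a subunit of calprotectin, rose from 8.52 ± 3.11 to 26.1 ± 11.2 TPM (adjusted p = 0.00618, 0.272 after scaling). Cfd, the adipocyte protease adipsin, rose from 31.5 ± 16.7 to 82.7 ± 12.9 TPM, and the haemoglobin-binding protein Hp from 3.75 ± 2.27 to 11.2 ± 1.90 TPM. Il1f6, which encodes the cytokine IL-36α, rose from 1.21 ± 0.49 to 4.12 ± 1.44 TPM. Clca4b rose from 2.40 ± 0.41 to 6.72 ± 2.41 TPM. Scaled adjusted p-values of these 4 lay between 0.248 and 0.334. S100a8, the partner of S100a9, filled the tenth place and did not pass, at 10.7 ± 3.11 and 23.6 ± 7.28 TPM (adjusted p = 0.0626).

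On the lower side, Cxcl13 fell from 9.57 ± 2.46 to 3.67 ± 1.07 TPM (limma log2 fold change −1.28 ± 0.26, adjusted p = 0.0183). After scaling its log2 fold change was −1.305 (limma adjusted p = 0.156). Cyp26b1 fell from 3.44 ± 0.88 to 1.0 ± 0.40 TPM (adjusted p = 0.0293, 0.287 after scaling). Krt25, a keratin of the hair root sheath, fell from 11.9 ± 9.02 to 2.35 ± 0.74 TPM, Tchh (trichohyalin) from 9.39 ± 6.66 to 1.99 ± 0.85 TPM, and Krtap5-1 from 3.68 ± 2.10 to 0.453 ± 0.543 TPM. Their scaled adjusted p-values lay between 0.32 and 0.351, with log2 fold changes of −1.819, −1.767 and −2.121 after scaling (−1.801, −1.747 and −2.105 before). Krt71 and Krtap5-2, of the same kind, also fell; these were chosen after their values were seen. Krtap5-5, Krtap17-1, Krtap28-13, Ankrd26 and Syt8 filled the ranking and did not pass (adjusted p from 0.0767 to 0.227). Keratin-associated genes are near-identical within their family, so their separate values are uncertain.

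**Figure D2:**
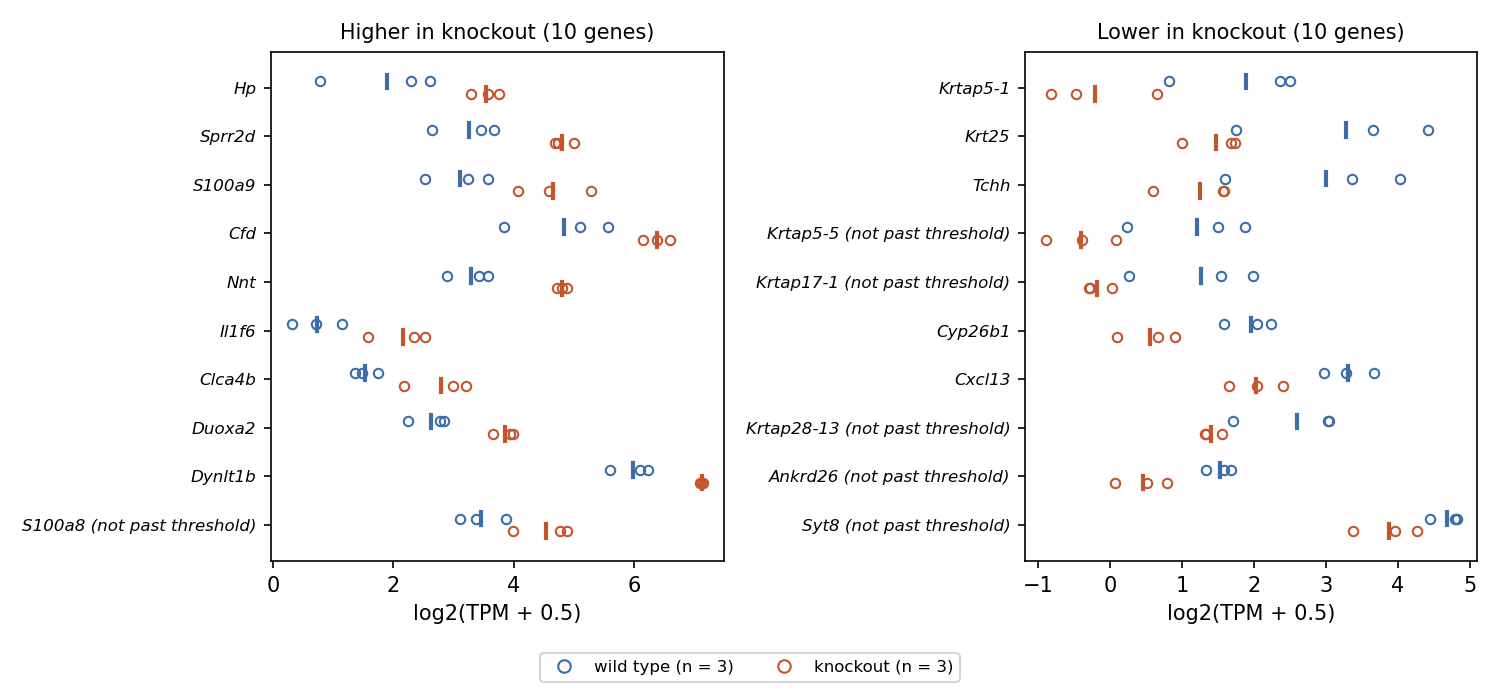
Each circle is the log2(TPM + 0.5) of 1 library for the 10 genes named in each direction, in wild type (blue) and knockout (red), with the group means as vertical bars (n = 3 each). Genes were drawn only if all 3 knockout libraries lay on 1 side of the 3 wild-type libraries, so this separation is a rule of selection. The genes marked as not past the threshold had limma adjusted p-values from 0.0626 to 0.227.

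The remaining genes past the threshold were of less certain identity. Among those higher were 1 predicted gene, 2 pseudogenes and 1 immunoglobulin segment. Among those lower were 9 predicted genes, 2 pseudogenes and 7 immunoglobulin segments. Such segments share sequence, and 62 of the 89 tested had a lower mean in knockout. Of the 25 lower genes, 6 were hair keratin, keratin-associated or trichohyalin genes by name, among them the pseudogene Krtap19-9a. The predicted genes Gm4553, Gm10153 and Gm7579 lie beside or between Krtap5-2 and Krtap5-1 on chromosome 7. Gm9507, Gm10100, Gm10318 and Gm2696 lie close together on chromosome 10. These were named after their values were seen. Gm14292 had 0, 0 and 0.037 TPM in wild type and 7.09 ± 1.31 TPM in knockout, and Gm21836 had 4.34 ± 2.46 TPM in wild type and was listed at 0 in each knockout library. The groups did not overlap for 712 genes, or 4.98%, where chance gives 10% for 3 against 3, and 528 genes had an unadjusted p below 0.05.

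Single transcripts were compared to see changes that gene totals hide. B4galnt3 and Mgat4a, which encode glycosyltransferases, each had a transcript that fell, and Atg7, an enzyme of autophagy, had a transcript that rose. B4galnt3 lies within 10 Mb of Tnfrsf1a and Atg7 within 20 Mb. For both, sequence flanking the targeted allele cannot be told apart from an effect of the knockout. The B4galnt3 transcript is annotated as a processed transcript and not as protein coding. B4galnt3 ENSMUST00000125341 fell from 25.9 ± 6.10 to 1.20 ± 0.70 TPM (SD, n = 3; limma log2 fold change −4.04 ± 0.35, adjusted p = 0.00234, 0.0458 after scaling). Atg7 ENSMUST00000182035 rose from 1.01 ± 0.24 to 8.36 ± 0.77 TPM (adjusted p = 0.0048, 0.00889 after scaling). Mgat4a ENSMUST00000042161 fell from 32.2 ± 13.2 to 6.36 ± 1.73 TPM (adjusted p = 0.0399, 0.161 after scaling). Nnt ENSMUST00000099149 rose from 8.27 ± 1.63 to 26.9 ± 1.60 TPM (adjusted p = 0.033, 0.0055 after scaling).

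Transcripts of Rbm39, Lhfpl2 and Hspa8 were listed at 0 in each wild-type library and at 7.18 ± 2.76, 6.54 ± 2.64 and 6.69 ± 4.73 TPM in knockout, while a Trim26 transcript had 3.28 ± 0.97 TPM in wild type and 0.032 TPM or less in knockout. Those of Hspa8 and Trim26 are likewise annotated as processed transcripts. Transcripts of Erdr1 and of its near copy Gm21887 also rose and cannot be separated with certainty. After scaling, the transcripts of Hspa8, Erdr1 and Gm21836 did not pass (limma adjusted p = 0.176, 0.0532 and 0.0532), nor did that of Mgat4a. In all, 9 transcripts were higher and 4 lower of 31056 tested, from 13 genes, and 4 of these genes also passed in the test of gene totals. The transcripts other than that of Tnfrsf1a were chosen after their values were seen. Without wild-type replicate 2 the number fell to 1, and without knockout replicate 1 it was 57.

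TNF signalling is the pathway that loss of TNFR1 interrupts most directly, and no gene of its 2 fixed lists passed the threshold. None of 26 tested NF-κB target genes of TNF passed the threshold, over all genes or adjusted over the list alone, and their median log2 fold change was 0.03 (camera adjusted p = 0.4). Cxcl10 had 1.32 ± 0.27 TPM in wild type and 3.28 ± 2.38 TPM in knockout, and Bcl3 18.7 ± 5.39 and 28.1 ± 6.91 TPM. None of 21 genes of TNF receptor signalling passed either (median 0.03, camera adjusted p = 0.733). Tradd had 125.6 ± 17.5 TPM in wild type and 150.5 ± 11.5 TPM in knockout, and Traf2 12.9 ± 2.45 and 15.1 ± 1.04 TPM. None of 24 interferon-stimulated genes passed (median 0.03, adjusted p = 0.917). With wild-type replicate 2 left out the 3 medians were −0.07, −0.09 and 0.09, against −0.13 for all genes. By camera with the preset correlation, the NF-κB target list then had an adjusted p of 0.0516. The interferon list was then past the threshold by the same test (adjusted p = 3.95e-05). An estimated correlation was not tried in that fit. Over all 6 libraries, camera with an estimated correlation gave the interferon list an adjusted p of 0.977.

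Genes of B cells and of the stroma of lymphoid follicles were lower as groups in the knockout colon. All 21 tested members of the B and plasma cell list had negative log2 fold changes, with a median of −0.72 (camera adjusted p = 1.15e-20; adjusted p = 0.522 with an estimated correlation). None passed over all genes, and 11 were lower adjusted over the list alone. Ighd, the heavy chain of IgD, had 7.98 ± 2.33 TPM in wild type and 3.53 ± 2.39 TPM in knockout, and the IgM receptor Fcmr 3.96 ± 1.52 and 1.69 ± 1.30 TPM. All 10 members of the lymphoid stroma list were negative, with a median of −0.54 (camera adjusted p = 5.98e-13; adjusted p = 0.522 with an estimated correlation). Cxcl13 passed, and 5 were lower adjusted over the list alone. With single libraries left out, the B and plasma cell median ran from −1.101 without knockout replicate 3 to −0.398 without knockout replicate 2, and the lymphoid stroma median from −0.92 to −0.355 in the same fits.

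The level of the B cell list, as the geometric mean of TPM + 0.5, was 4.94, 4.80 and 6.78 in wild-type replicates 1, 2 and 3 and 3.28, 2.22 and 5.35 in the knockout replicates. The groups overlapped (exact permutation p = 0.3), since knockout replicate 3 lay within the wild-type range. The T and NK cell list had a median of −0.11 over 7 members (Cd2, Trbc1) and the macrophage and dendritic cell list −0.05 over 15 (Csf1r), and neither passed (camera adjusted p = 0.262 and 0.4).

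Genes of antimicrobial defence and of neutrophils were higher as groups. The 16 antimicrobial genes had a median of 0.36 (camera adjusted p = 2.68e-10; adjusted p = 0.531 with an estimated correlation). Duoxa2 and S100a9 passed, and 4 were higher adjusted over the list alone. Of 15 neutrophil genes listed, 6 were tested and all were positive, with a median of 0.69 (camera adjusted p = 9.78e-09, and adjusted p = 0.522 with an estimated correlation). S100a9 passed, and 3 were higher adjusted over the list alone. S100a8 and S100a9 belong to both lists, so these results are not independent. A rise in the number of neutrophils is not shown by them. The neutrophil median was 0.13 with no filter on low values and 1.087 with a filter at 5 TPM. When wild-type replicate 2 was left out, the medians were 0.21 and 0.36, while the median of all genes moved from 0.03 to −0.13. Lists of skeletal muscle, squamous epithelium and adipocytes were higher as well (medians 1.39, 0.63 and 0.68; adjusted p = 0.522, 0.531 and 0.522 with an estimated correlation), and the levels of all 5 lists were lowest in wild-type replicate 2.

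Lists of the epithelium were slightly higher. Goblet cell genes had a median of 0.29 with 15 of 16 members positive (camera adjusted p = 2.89e-06; adjusted p = 0.807 with an estimated correlation). The trefoil peptide Tff3 had 2078 ± 345.8 TPM in wild type and 2744 ± 31.4 TPM in knockout, and the secretory lineage factor Atoh1 26.1 ± 8.99 and 36.6 ± 0.77 TPM. Enteroendocrine genes had a median of 0.32 with 12 of 13 positive (camera adjusted p = 0.000136; adjusted p = 0.807 with an estimated correlation). The hormone gene Insl5 had 78.7 ± 24.1 and 133.5 ± 9.77 TPM, and the serotonin synthesis enzyme Tph1 4.52 ± 1.67 and 8.30 ± 1.60 TPM. No member of either list passed over all genes, and 0 goblet and 2 enteroendocrine genes were higher adjusted over the list alone. These medians were 0.12 and 0.11 without wild-type replicate 2, where the median of all genes was −0.13.

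All 16 absorptive colonocyte genes were positive (median 0.23, camera adjusted p = 0.000268; adjusted p = 0.807 with an estimated correlation), among them Saa1 and Slc6a14. Distal colon genes had a median of 0.26 (adjusted p = 0.000782; adjusted p = 0.831 with an estimated correlation), with 2 of 10 higher adjusted over the list alone. The water channel Aqp4, in this list, had 8.56 ± 2.11 and 13.8 ± 2.04 TPM. Ion and water transport had a median of 0.19 (adjusted p = 0.00335; adjusted p = 0.892 with an estimated correlation), with 1 of 19 higher adjusted over the list alone; its sodium-hydrogen exchanger Slc9a3 had 3.49 ± 1.23 and 6.89 ± 1.47 TPM. Epithelial junction genes, such as Cldn4 and Dsg2, had a median of 0.17 (adjusted p = 0.00162; adjusted p = 0.936 with an estimated correlation). The 4 medians without wild-type replicate 2 were 0.13, 0.07, 0.07 and 0.02, against −0.13 for all genes.

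Among metabolic lists, fatty acid oxidation had a median of 0.19 (camera adjusted p = 0.000429; adjusted p = 0.892 with an estimated correlation), with Pdk4 at 4.55 ± 1.86 and 7.49 ± 0.24 TPM and Angptl4 at 1.88 ± 0.62 and 3.51 ± 1.02 TPM. Oxidative phosphorylation, with Sdha and Ndufa1, had a median of 0.15 (adjusted p = 0.00255; adjusted p = 0.936 with an estimated correlation). These medians were 0.05 and −0.001 without wild-type replicate 2, against −0.13 for all genes. Cholesterol synthesis was lower, with a median of −0.11 (adjusted p = 0.0198; adjusted p = 0.936 with an estimated correlation), Insig1 at 69.6 ± 3.39 and 51.6 ± 9.54 TPM and Lss at 17.7 ± 3.82 and 13.1 ± 1.60 TPM. Its median was 0.05 without wild-type replicate 1 and −0.25 without wild-type replicate 2. Extracellular matrix genes had a median of −0.18 (adjusted p = 7.29e-05; adjusted p = 0.892 with an estimated correlation), with Postn at 223.3 ± 42.9 and 161.2 ± 24.7 TPM and Eln at 33.5 ± 6.92 and 22.6 ± 7.93 TPM. Its median was 0.02 without knockout replicate 2 and −0.33 without wild-type replicate 2. No member of these 4 lists passed, over all genes or adjusted over the list alone.

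Markers of skeletal muscle, squamous epithelium and adipocytes were higher as groups in the knockout colon, and their levels varied widely within wild type. The level of the 15 skeletal muscle genes was 93.3, 7.49 and 23.1 in wild type and 40.0, 106.1 and 57.9 in knockout (median log2 fold change 1.39, camera adjusted p = 1.15e-20; adjusted p = 0.522 with an estimated correlation). Among its members, which include Actn3, Myh4 had 0.259 ± 0.240 TPM in wild type and 3.34 ± 3.77 TPM in knockout. Squamous epithelium, with the epidermal genes Lor and Krtdap, had levels of 70.8, 18.1 and 51.7 in wild type and 68.5, 51.8 and 69.0 in knockout (median 0.63, adjusted p = 1.58e-12; adjusted p = 0.531 with an estimated correlation). Adipocyte genes, with Cfd past the threshold, had levels of 16.0, 6.98 and 13.3 in wild type and 16.2, 18.0 and 21.1 in knockout (median 0.68, adjusted p = 1.94e-15; adjusted p = 0.522 with an estimated correlation). Adjusted over the list alone, 14 muscle, 5 squamous and 8 adipocyte genes were higher. Wild-type replicate 2 was lowest in all 3 lists, and without it the medians were 0.33, 0.05 and 0.31, against −0.13 for all genes. Without wild-type replicate 1 the list medians were 2.45, 1.054 and 0.909, against 0.11 for all genes.

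**Figure D3:**
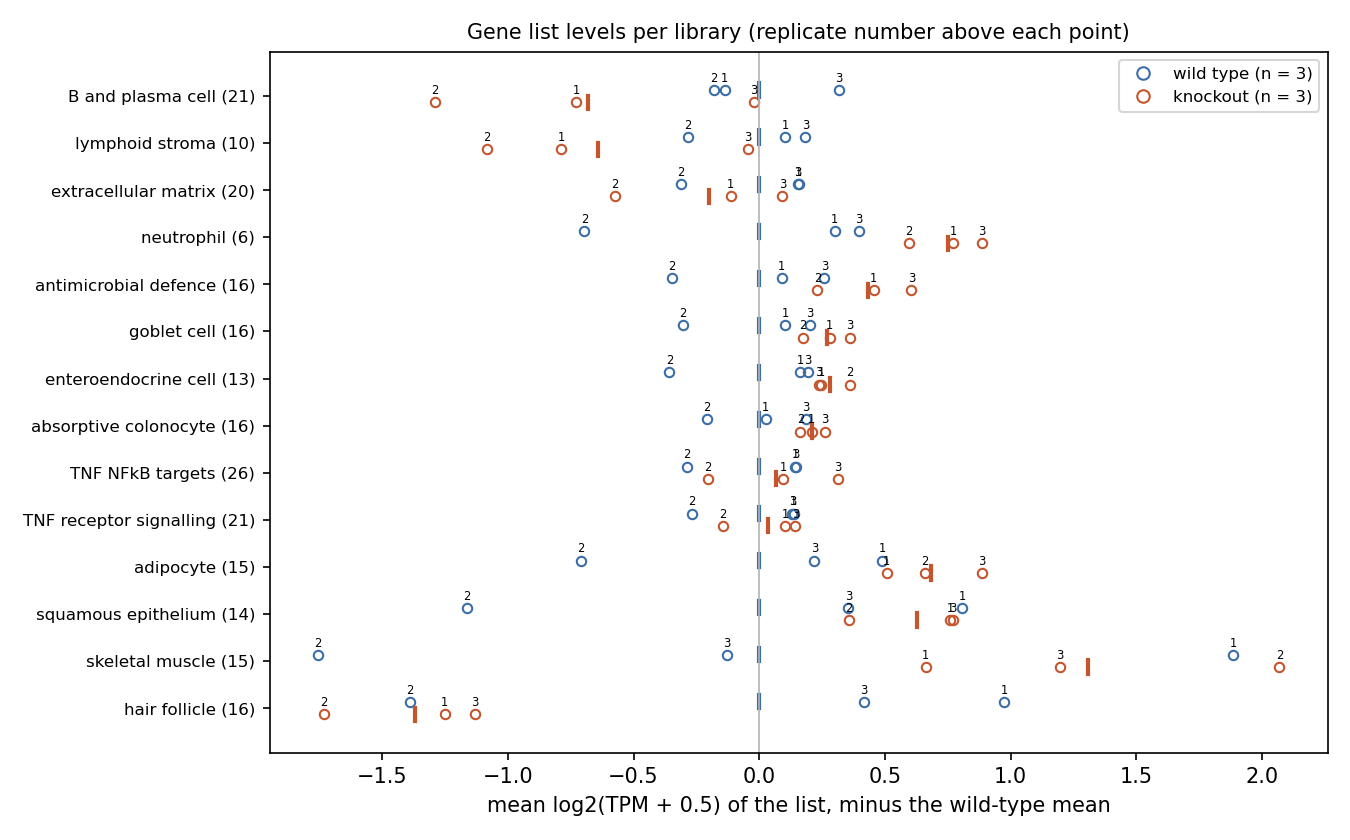
Each circle is the mean log2(TPM + 0.5) of a gene list in 1 library, minus the mean of the 3 wild-type libraries, with the number of genes in brackets, the replicate number above each circle and group means as vertical bars (n = 3 each). Wild-type replicate 2 lay lowest among wild type in all 14 lists drawn. The hair follicle list was written after the data were seen.

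In all, 13 lists were higher and 4 lower of 39 tested by camera with the preset correlation, and none passed with an estimated correlation (lowest adjusted p = 0.522) or by fry (lowest adjusted p = 0.922). After median-of-ratios scaling, camera with the preset correlation gave these 17 lists adjusted p-values between 6.78e-07 and 0.0152. No member of the remaining tested lists passed, over all genes or adjusted over the list alone. Beyond those given above, these were xenobiotic metabolism, heat shock, immediate early, smooth muscle, cell cycle, endothelium, fibroblast, enteric neuron, enteric glia, endoplasmic reticulum stress, stem and crypt, small intestine, proximal colon, antigen presentation, circadian clock, interstitial cells of Cajal and tuft cells. Their medians lay between −0.09 and 0.18 and their adjusted p-values between 0.0508 and 0.942. After scaling, xenobiotic metabolism and heat shock were higher (adjusted p = 0.017 and 0.0286) and smooth muscle, cell cycle and fibroblast genes lower (0.00437, 0.0453 and 0.0466) by camera with the preset correlation; with an estimated correlation and TPM as deposited the adjusted p of each was 0.936. Pancreas, red blood cell and mast cell lists had fewer than 5 tested genes, none past the threshold. The Y-linked genes Ddx3y (19.3 ± 3.95 and 17.6 ± 2.75 TPM) and Kdm5d (9.14 ± 1.20 and 7.62 ± 1.38 TPM) were present in both genotypes. Of 3 genes known to differ between substrains, Nnt rose and Wdfy1 (17.4 ± 4.27 and 12.9 ± 2.35 TPM) and Entpd4 (31.3 ± 4.86 and 29.4 ± 3.16 TPM) did not pass.

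Genes close to Tnfrsf1a were compared with the rest, since a targeted allele can bring sequence of another strain with it. Of 159 tested genes within 10 Mb, none passed the limma threshold, against 38 of 14063 elsewhere (two-sided Fisher's exact test, p = 1). With only 0.27% passing elsewhere, so few neighbours could show little. At an unadjusted p below 0.01, a threshold chosen after seeing the data, 5 of 159 genes (3.15%) and 207 of 14063 (1.47%) differed (Fisher's exact test, p = 0.0895). Ankrd26 was the neighbour with the smallest p, at 2.40 ± 0.36 TPM in wild type and 0.897 ± 0.340 TPM in knockout. Among single transcripts, those of B4galnt3 and Atg7, within 20 Mb of Tnfrsf1a, did pass the threshold.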

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

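These settings, and the unadjusted p of 0.01 used near Tnfrsf1a, were chosen after seeing the data: array weights, rescaling over transcripts with a gene, and median-of-ratios scaling without wild-type replicate 2. The count of 38 genes kept within 1.5 times of its value with either pseudocount, without the variance trend, at an adjusted p of 0.1 and with transcripts of at least 0.1 TPM. It was 2 with no filter on low values, 142 with a filter at 5 TPM, 6 after median-of-ratios scaling, 7 after quantile normalization, 83 with robust variance estimation, 141 without immunoglobulin and mitochondrial genes, 122 with array weights, 4 after rescaling over transcripts with a gene and 21 after median-of-ratios scaling without wild-type replicate 2. Calls went up to 307 without wild-type replicate 1 and down to 19 without wild-type replicate 2; they were 123 without wild-type replicate 3 and 202, 171 and 209 without knockout replicates 1, 2 and 3. All 38 genes remained without wild-type replicate 1, and 8 without wild-type replicate 2. After median-of-ratios scaling 5 genes were higher and 1 lower, against 13 and 25. That scaling raised the number of genes with an unadjusted p below 0.05 from 528 to 1622, and lowered the prior degrees of freedom of limma from 24.1 to 3.18. The median log2 fold change of all genes was 0.03, and it was −0.13 without wild-type replicate 2, 0.11 without wild-type replicate 1 and −0.10 after rescaling over transcripts with a gene. The count of 13 transcripts was 7 with a pseudocount of 0.1, 1 with no filter, 23 with a filter at 5 TPM, 28 at an adjusted p of 0.1, 42 with array weights and 2 after median-of-ratios scaling without wild-type replicate 2. It ran from 1 without wild-type replicate 2 to 57 without knockout replicate 1, with 20 and 21 without wild-type replicates 1 and 3 and 21 without knockout replicate 2. The 17 gene lists became 0 with an estimated correlation and 0 by fry, and their number stayed within 1.5 times elsewhere. Within 10 Mb of Tnfrsf1a the count of 0 genes became 1 with a filter at 5 TPM, 2 with robust variance estimation, 2 with array weights and 1 without immunoglobulin and mitochondrial genes; it ran from 0 without wild-type replicate 2 to 2 without knockout replicate 1, with 1 without wild-type replicate 1. Signs reversed for oxidative phosphorylation with array weights (median −0.009) and without wild-type replicate 2 (−0.001, against up to 0.241 with another library left out), for cholesterol synthesis (from −0.25 to 0.045, the latter without wild-type replicate 1), for extracellular matrix (from −0.336 to 0.015, the latter without knockout replicate 2) and for Entpd4 (from −0.215 to 0.008, the latter without knockout replicate 2). The cause was not tested. The summed Tnfrsf1a value kept its direction and did not pass in any setting (log2 fold change from −0.61 to −0.26). Of the 19 named genes past the threshold, none reversed under any setting, with 264 of the values past the threshold and 109 not. Gm14292 was below 0.05 in 19 of 19 settings, Nnt and Dynlt1b in 19 of 20, Sprr2d in 18 of 20, Duoxa2 in 17 of 20, S100a9 in 14 of 20 and Tchh in 11 of 20. These tallies include the fits with infinite prior degrees of freedom. The labels give no shared litter, batch or day for samples of the same replicate number. Their deviations from the group means correlated at 0.052, 0.132 and 0.184 for numbers 1, 2 and 3. Of the 6 libraries, 5 correlated best with their own number across genotypes, a hint from the data and not the design, and knockout replicate 1 did so with wild-type replicate 3 (0.098). The replicate block gave 71 genes, 1 transcript and 18 lists. Count models and DESeq2, listed in advance for estimated counts, were not run because the table gives TPM alone, and TPM keeps no depth, so counting error could not be separated from the spread between mice.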

Other observations

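The tests of perianal skin, flanking sequence, immune cells of all kinds, hair against squamous genes, all-or-none transcripts and transcripts near Tnfrsf1a were chosen after the results they measure were seen, and so were the genes named below. Several genes beside Tnfrsf1a on chromosome 6 had an unadjusted p below 0.01 without passing the adjusted threshold. The condensin subunit gene Ncapd2 had 35.2 ± 8.15 TPM in wild type and 21.8 ± 3.61 TPM in knockout (SD, n = 3). Gprc5a had 86.1 ± 23.4 TPM in wild type and 129.7 ± 17.1 TPM in knockout, and its relative Gprc5d had 2.83 ± 1.81 and 0.755 ± 0.255 TPM. Of single transcripts other than those of Tnfrsf1a, 2 of 506 within 20 Mb passed the limma threshold, those of B4galnt3 and Atg7, against 10 of 30424 elsewhere (Fisher's exact test, p = 0.0158). Within 10 Mb it was 1 of 344 against 11 of 30586 (Fisher's exact test, p = 0.126).

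Transcripts without a gene were dominated by a pair that measured 174580 and 94692 TPM in wild-type replicate 2 and 43027 and 23856 TPM in knockout replicate 2. In the other libraries the first of them lay between 9714 and 23470 TPM. Lars2, which encodes the mitochondrial leucyl-tRNA synthetase, was highest in the same libraries, at 15544 TPM in wild-type replicate 2 and 4225 TPM in knockout replicate 2, against 805.6 to 2249 TPM in the others. Mitochondrially encoded genes held 10.7, 9.19 and 11.4% of TPM in wild type and 14.2, 12.9 and 12.8% in knockout.

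Hair follicle genes had a lower mean in the knockout libraries, with list levels of 2.25, 1.61 and 2.44 against 10.5, 2.04 and 7.14 in wild-type replicates 1, 2 and 3. A list of hair keratins and root sheath genes, written after the data were seen, had 16 tested members with a median log2 fold change of −1.64 and quartiles of −1.71 and −1.10. Less perianal skin in the knockout dissections was expected to lower epidermal genes about as much. The squamous epithelium list had a median of 0.633, and 0.046 without wild-type replicate 2. That list is not limited to skin that bears hair, so less hairy skin in the knockout dissections is not excluded. The hair list overlapped between the groups with TPM as deposited and not after median-of-ratios scaling, nor did the log2 level of hair minus squamous genes (−2.755, −3.147 and −2.857 in wild type, −4.932, −5.007 and −4.821 in knockout), but the hair genes were chosen for their lower values, so this spacing tests nothing. A different hair cycle stage in the skin taken along, or an effect of genotype on the follicle, may also account for the pattern, and neither was tested.

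A pseudogene, a predicted gene and single transcripts of other genes, on several chromosomes, were present in 1 genotype and nearly absent in the other. A strain difference at loci away from Tnfrsf1a may explain this, since C57BL/6J is known to carry a deletion in Nnt that other strains lack, and Nnt was higher in all 3 knockout libraries. Genes at 2 TPM or more in all libraries of 1 group and at 0.1 TPM or less in the other numbered 2 (Gm14292 and Gm21836), and the highest count of the other 9 splits was 1. Gm21836 is very short (chromosome 9, 124493731 to 124493793), so its TPM is uncertain. For transcripts the count was 8, from Lhfpl2, Trim26, Rbm39, Gm14292, Fastk, Hspa8, Gm21836 and Phf6, and the highest other was 6, so a strain difference and an uneven draw of samples cannot be told apart with 10 splits. Donor sequence flanking the targeted allele does not account for the 2 genes, since 0 of them lay within 10 Mb of Tnfrsf1a.

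B cell and lymphoid stroma genes were lower in the knockout libraries. A single wild-type library carrying a lymphoid follicle would not leave the B cell median as low as it was: with each wild-type library left out in turn, the highest median was −0.579. Fewer immune cells of all kinds would lower T cell and macrophage genes alike, but the lower quartile of those 22 genes was −0.147, above the B cell median of −0.72. Of these 22, however, 15 were macrophage and dendritic cell genes. Only 7 of 24 T and NK cell genes were tested, with a lower quartile of −0.309. They had low values, such as Cd2 at 1.445 and 0.893 TPM, where the scale understates change. A fall of lymphocytes in general is therefore not excluded. Also open is how many lymphoid follicles each colon sample held, since knockout replicate 3 (5.35) exceeded wild-type replicates 1 and 2 (4.94 and 4.80) in B cell level. An effect of TNFR1, which is known to be needed for follicular dendritic cell networks, may also contribute and was not tested apart from this.

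The 6 libraries can be split into groups of 3 in 10 ways, too few for a share below 0.05. The genotypes gave 38 genes, and the highest of the other splits gave 65, so that 2 of the 10 splits gave at least as many. For transcripts the genotypes gave 13 and the highest other 3, with 1 split as large, the real one. For gene lists the genotypes gave 17 and the highest other 23, with 4 splits as large.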
